A study of Homo sapiens with 7 samples.

How the data were processed

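RNA of SETDB1 knockdown clones and of scrambled controls was measured on 7 Agilent 2-colour arrays of 62976 spots. Per the labels, each array compared a knockdown clone, labelled with Cy5, with the control RNA of its cell line, labelled with Cy3, and 1 dye-swap array per line held the pooled clones in Cy3 and the control in Cy5. The source labels call each of these clones a pooled clone, and those of clones 30 and 31 print DMS-272 and DMS-271 where the cell line tags and the controls read DMS-273. Each was treated as 1 clone of the line in its tag, which the labels alone do not settle. Clones were taken as the replicates, 3 for DMS-273 and 2 for NCI-H1437, and the dye-swap arrays were not counted as replicates. They gave the dye effect, so that a line's mean ratio is the average of its forward mean and its turned dye-swap value, and they entered the filter on dim probes, the slide averages, the 2-fold rule and the rule of 1 sign on every array. Because the pool on the swap array holds each clone of its line, a clone that was left out still entered the line's mean through that array. The deposited scanner files were made by the authors with Feature Extraction 10.7.3.1 and hold, per the file headers, the median pixel intensity of each spot and of its local background in each channel, without normalization. The planned use of mean signals was changed to the median signals, since the files hold only those. The same files hold log10 ratios of Cy5 over Cy3, which per the file headers the software had background-subtracted and dye-normalized. The deposited table of the series holds processed log2 ratios. Comparison with the scanner ratios showed knockdown over control on each array, with the dye-swap columns already turned and the values shrunk towards 0, and how the authors made them is not stated. Both the software's ratios and this table were used as alternatives.

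Signals were background-corrected with normexp (offset 50) and loess-normalized within arrays in limma 3.58.1 under R 4.3.3, with control spots at weight 0, and the data were handled with the data.table package, version 1.17.8. Spots marked as outliers were left out and spots of a probe averaged, which gave 50599 probes, of which 29 were dropped. Probes were named by their RefSeq accession in a gene table of GRCh38.p14. This matched 28154 probes (55.7%), and the other 22416 kept their accession as the name. The probe with the highest mean intensity stood for each of 41157 names. The dye effect of a probe in a line was the mean of its forward average and its dye-swap value, and was subtracted from each clone's ratio (SD 0.118 in DMS-273 and 0.122 in NCI-H1437, r = 0.704 across genes). A gene was tested in a line when the knockdown channel or the control channel was well above background on every array of the line. Where the other channel was above background on no array of the line the fold is a bound, and where it was so on some arrays the ratio is given with their number. The bound is computed from the mean of the bright channel and, for the other, the lowest signal that was well above background on the array or the spot's own signal if higher.

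Each line's mean ratio was tested against 0, two-sided, with lmFit and eBayes in limma, which pooled the spread of the 5 clones (3 residual and 3.436 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The difference between the lines was a contrast in the same fit over genes tested in either line. Values within a slide were averages over its arrays of the line, with the dye-swap array turned and no dye correction. A fixed rule counted genes of at least 2-fold and 1 sign on each array of a line. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a line, and an estimated correlation was the alternative. The 29 lists covered chromatin partners and silencing targets (HOX, ZNF, protocadherin, cancer-testis, retrovirus-derived and imprinted genes), interferon, antigen presentation and inflammatory genes. They also covered p53 targets, tumour suppressors, cell cycle, WNT and YAP/TEAD genes, cell identity (epithelial, mesenchymal, neuroendocrine, lung), stress and metabolism, ribosomal and histone genes, genes near SETDB1, and leukocyte and endothelial markers. Expected numbers of shared genes were the products of the margins over genes tested in both lines.

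The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named SETDB1, the 12 highest and 12 lowest mean ratios per line among passing genes with a symbol and 1 sign on every array, up to 4 members per list by lowest p, and the 10 genes of lowest p per sign for the difference. Pseudogenes, near-identical family members and uncharacterised loci could be left out of the prose, and members named for a list were chosen from those 4. Of the genes that the rule names for the difference, 1 is not reported here. Tested on simulated data with known changes, the procedure called 98.5% of 2-fold changes in DMS-273, 86.6% in NCI-H1437 and 70.7% for the difference. At 1.5-fold these shares were 67.2%, 47.8% and 22.7%, and 8.76%, 6.06% and 3.41% of the calls fell on unchanged genes. Planted 4-fold changes were measured at a median log2 size of 1.62 in DMS-273 and 1.81 in NCI-H1437, below the planted size. Fold sizes may therefore be too small. The simulation planted the same change in each clone of a line and let the genes deviate independently. It changed few genes, and it held no error of the control RNA. These shares may therefore not hold for the real arrays. Alternatives covered background correction, normalization, the filter on dim probes, probe choice, the dye correction, the fit, the slide as a block, thresholds and leaving out each clone. Removing the median of the 50 nearest tested genes on the chromosome, and testing genes of known position alone, were added after the data were seen. In lists whose members lie side by side, removing the neighbouring median takes out part of the list's own shift. These are the genes near SETDB1, the protocadherins and clustered histone genes, and a smaller mean or lost call there is no test of the list. Groups of 3 and 2 clones were too small for the tests of outlying samples and of random splits. The median signal of an array was 46 to 72 in Cy3 and 84 to 115.5 in Cy5, over backgrounds of 22 to 32 and 53 to 55.5, and 0 spots were saturated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.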

Results

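The series compared the transcripts of human lung cancer cells depleted of SETDB1, a histone H3 lysine 9 methyltransferase that represses transcription, with those of control cells that carried a scrambled hairpin. Depletion was by short hairpin RNA in DMS-273, a small cell lung cancer line, and in NCI-H1437, a non-small cell (adenocarcinoma) line. The 7 arrays comprised 3 knockdown clones of DMS-273 (clones 21, 30 and 31), 2 of NCI-H1437 (clones 56A and 56B), and 1 dye-swap array per line with the pooled clones of that line. The source labels call each of the 5 clones a pooled clone and print DMS-272 for clone 30 and DMS-271 for clone 31, so that n rests on taking each as 1 clone of the line in its cell line tag. Each array held 58717 spots for transcripts, and 46.1% to 59.7% of them were well above background in a channel. Ratios are log2 of knockdown over control, as the mean ± SD of the clones (n = 3 for DMS-273 and n = 2 for NCI-H1437), and negative values are lower in the knockdown clones. Every limma p-value of a gene measured the spread between clones against 1 control RNA per line. It left out the control's own spread and the error of the dye-swap array that enters the line's mean. The camera p-values of lists compared a list's genes with the other genes, at a preset or an estimated correlation. Permutation p-values came from shuffled genes. The number of arrays limited the precision.

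The first comparison asked how far the targeted transcript fell. SETDB1 (chromosome 1, 150926000 to 150964737 in GRCh38.p14) fell to 24.9% of its control level in DMS-273, a log2 ratio of -2.01 ± 0.45 (adjusted p = 0.00133, limma). Its ratios were -2.09 in clone 21, -2.41 in clone 30 and -1.51 in clone 31, and the dye-swap array gave -2.003. In NCI-H1437 SETDB1 fell to 37.9% of control, a log2 ratio of -1.40 ± 0.0079 (adjusted p = 0.00706), with -1.39 in clone 56A, -1.41 in clone 56B and -1.45 on the dye-swap array. The other SETDB1 probes gave -2.77 and -2.51 in DMS-273 and -1.40 and -1.25 in NCI-H1437. The difference between the lines was -0.60 and did not pass (adjusted p = 0.168). Slide 1 held clones 21, 31 and 56A and the NCI-H1437 swap, and slide 2 held clones 30 and 56B and the DMS-273 swap. SETDB1 was -1.81 and -2.21 on slides 1 and 2 in DMS-273 and -1.40 and -1.35 in NCI-H1437. With the slide as a block the means were -2.09 and -1.34, and the difference between the lines was -0.76 and passed (adjusted p = 0.0281), as it did without clone 31 (-0.73, adjusted p = 0.0485) and with 1 dye effect for both lines (-0.63, adjusted p = 0.0444). Over all settings its adjusted p ranged from 0.0281 to 0.351.

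The comparison in DMS-273 asked which transcripts changed in the small cell line. The genes that rose most in DMS-273 included TGFBI, a matrix protein induced by TGF-beta (4.02 ± 2.18), LGALS1, which encodes galectin-1 (3.09 ± 1.97), and NNMT, which methylates nicotinamide (3.02 ± 2.11). PLAU, the urokinase plasminogen activator, rose by 2.78 ± 1.70, the matricellular gene CCN1 by 2.45 ± 1.71 and IGFBP7, a secreted binding protein of insulin-like growth factors, by 2.52 ± 1.37. MYOD1, the master regulator of skeletal muscle, rose by 2.55 ± 0.95, the placental hormone gene CSH1 by 2.43 ± 0.89 and the adhesion gene PCDHB13 by 2.62 ± 1.06. The antiviral gene SHFL rose by 2.65 ± 1.31, the transcriptional repressor BCL6 by 2.35 ± 0.54 and the long non-coding RNA D21S2088E by 3.86 ± 0.15. Among the genes that fell most, HEPACAM2, a cell adhesion gene, was at -3.56 ± 0.75, MAL2, which serves apical membrane traffic, at -3.42 ± 0.28 and PTPRZ1, a neural receptor phosphatase, at -2.74 ± 0.07. The lymphangiogenic growth factor VEGFD fell to -2.64 ± 0.29, the UDP-sugar receptor P2RY14 to -2.51 ± 0.17, the fructose transporter SLC2A5 to -2.22 ± 0.15 and the Ras activator RASGRP1 to -2.20 ± 0.23. The knockdown signal was well above background on 1 of 4 arrays for MAL2 and P2RY14 and on 3 of 4 for PTPRZ1 and VEGFD, as was the control signal on 3 of 4 for NNMT, so these ratios rest partly on signals near background. NINJ1, which mediates plasma membrane rupture, fell to -2.36 ± 0.13, SUSD3 to -2.33 ± 0.045, ASB9 to -2.72 ± 0.67 and DAPL1 to -2.96 ± 0.19, where the DAPL1 probes ranged from -2.96 to -1.03. CTAG1A, which encodes the cancer-testis antigen NY-ESO-1 and has a near-identical copy, fell to -2.43 ± 1.57. VEGFD and ASB9 lay in a run of 25 tested X chromosome genes, PRPS2 to SCML1, with a median of -0.56.

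Of 18917 genes tested in DMS-273, 3468 passed in the limma test, 1530 higher and 1938 lower, and 406 of these changed at least 2-fold. A fixed rule of 2-fold on each of the 4 arrays, without a test, took 192 genes, 54 higher and 138 lower. The passing genes had the same sign within slide 1 for 3462 of 3468 and within slide 2 for 3468. They were called on these same arrays, which largely fixed the shared sign, so it is no test of the slide. With the slide as a block 4758 genes passed. The number that passed was 503 without clone 21, 679 without clone 30 and 1808 without clone 31, and the 2-fold rule took 324 without clone 31, 145 of them higher. Calls of some named genes were lost without clone 21, with adjusted p of TGFBI (0.102), LGALS1 (0.135), NNMT (0.177), PLAU (0.188), SHFL (0.0688), PCDHB13 (0.0530), IGFBP7 (0.115), CCN1 (0.206), CSH1 (0.0521) and MYOD1 (0.0530). Without clone 30 they were TGFBI (0.0662), LGALS1 (0.107), NNMT (0.140), PLAU (0.159), SHFL (0.0775), PCDHB13 (0.0529), IGFBP7 (0.0926), CCN1 (0.177) and CTAG1A (0.122), and with an intensity trend and robust prior TGFBI (0.0900), LGALS1 (0.0958), NNMT (0.150), PLAU (0.0895), IGFBP7 (0.342) and CCN1 (0.0730). With the scanner software's log ratio LGALS1, PLAU, CCN1 and CTAG1A did not pass (adjusted p = 0.0576, 0.0634, 0.0799 and 0.0628), and over all settings the adjusted p of the 24 named genes ranged from 3.80e-07 to 0.342.

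**Figure D1:**
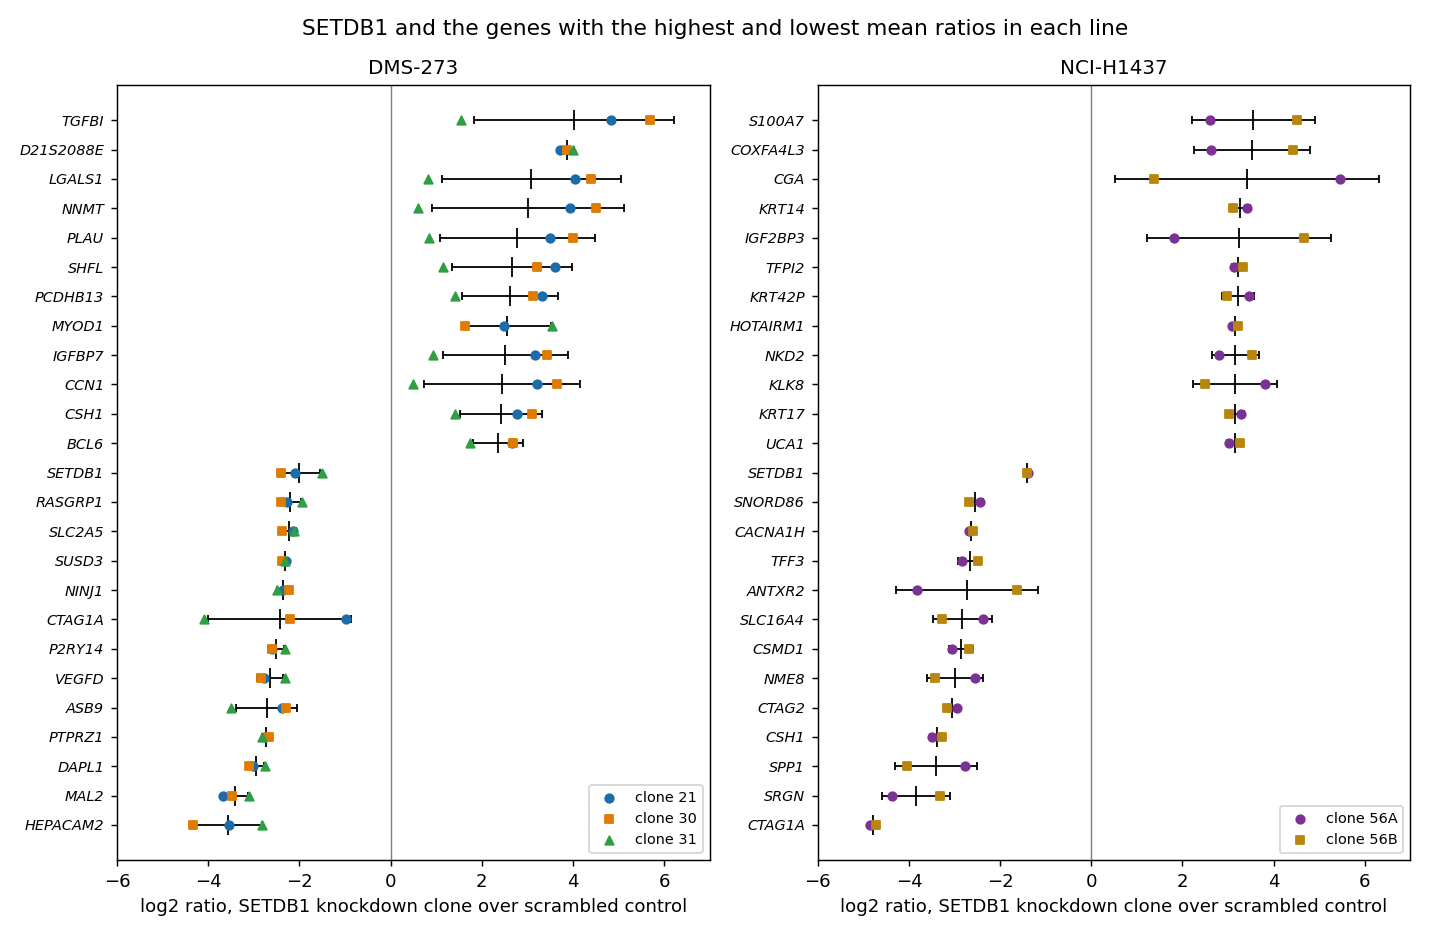
Log2 ratio of knockdown clone over scrambled control (horizontal axis) for SETDB1 and the 12 highest and 12 lowest named genes of each line (vertical axis), with a coloured point per clone and a black tick with bar for the mean ± SD. The DMS-273 points spread widely for TGFBI (4.02 ± 2.18) and closely for PTPRZ1 (-2.74 ± 0.07), and CGA spreads most in NCI-H1437 (3.41 ± 2.90).

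Of 29 gene lists, 7 shifted in DMS-273 with a preset correlation between genes. With an estimated correlation camera passed 0 of these lists, and 1 of the 29 had an unadjusted p under 0.05. Of 55 histone genes, 30 rose and 2 fell (33 and 2 adjusted over the list alone), and the core histone genes H4C11 (1.16 ± 0.14) and H3C2 (0.95 ± 0.13) were among the former. Their mean was 0.33 (adjusted p = 1.71e-10 by camera and adjusted p = 0.659 with an estimated correlation). It was 0.38 on slide 1, 0.32 on slide 2 and 0.35 with the slide as a block. H3C2 lay in a run of 25 genes, H4C2 to H3C8 on chromosome 6, with a median of 0.54, and the histone mean was 0.16 (adjusted p = 0.00144) with the median of neighbouring genes removed, an alternative chosen after the data were seen. That removal takes out part of the shift of histone genes that lie side by side. Of 64 mitosis genes, 20 rose and 0 fell (23 and 0 adjusted over the list alone), and the kinetochore gene NDC80 rose by 0.63 ± 0.075. Their mean was 0.19 (adjusted p = 4.46e-07 by camera and adjusted p = 0.659 with an estimated correlation). It was 0.18 on slide 1, 0.18 on slide 2 and 0.20 with the slide as a block. Of 425 zinc finger ZNF genes, 80 rose and 17 fell (87 and 18 adjusted over the list alone), a family whose KRAB members recruit SETDB1 through KAP1, and ZNF24, which has no KRAB domain, rose by 0.85 ± 0.13. Their mean was 0.11 (adjusted p = 2.13e-05 by camera and adjusted p = 0.150 with an estimated correlation). It was 0.11 on slide 1, 0.11 on slide 2 and 0.11 with the slide as a block. Of 17 clustered protocadherin genes, which mediate neuronal adhesion, 7 rose and 0 fell (10 and 0 adjusted over the list alone), including PCDHB9 (0.99 ± 0.16) and PCDHB13. Their mean was 0.52 (adjusted p = 1.65e-05 by camera and adjusted p = 0.528 with an estimated correlation). It was 0.50 on slide 1, 0.58 on slide 2 and 0.54 with the slide as a block. With the median of neighbouring genes removed, which takes out part of the shift of such clustered genes, the protocadherin mean was 0.34 (adjusted p = 0.103).

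Of 42 mesenchymal and extracellular matrix genes in DMS-273, 16 rose and 5 fell (19 and 7 adjusted over the list alone). Their mean was 0.50 (adjusted p = 0.0159 by camera and adjusted p = 0.874 with an estimated correlation). It was 0.28 on slide 1, 0.66 on slide 2 and 0.54 with the slide as a block. The growth factor receptor PDGFRA (1.64 ± 0.28) and the collagen gene COL1A2 (2.35 ± 0.57) rose, whereas the serine protease FAP (-1.93 ± 0.59) and COL5A2 (-1.59 ± 0.49) fell. The mesenchymal mean was 0.65 in clone 21, 0.82 in clone 30 and 0.029 in clone 31. Its call was lost without the dye correction (adjusted p = 0.0785). Of 30 cholesterol synthesis genes, 3 rose and 8 fell (3 and 9 adjusted over the list alone), among them the sterol isomerase EBP (-0.70 ± 0.19). Their mean was -0.16 (adjusted p = 0.0315 by camera and adjusted p = 0.874 with an estimated correlation). It was -0.16 on slide 1, -0.21 on slide 2 and -0.20 with the slide as a block. The EBP call was lost without clone 21 (adjusted p = 0.0548). The cholesterol list did not pass without clone 30 (adjusted p = 0.0776), with the scanner software's log ratio (0.0577), with genes of known position alone (0.0534) or with the median of neighbouring genes removed (0.127). Of 42 genes near SETDB1 on chromosome 1, 3 rose and 22 fell (4 and 25 adjusted over the list alone), the latter including MINDY1 (-1.38 ± 0.038) and GABPB2 (-1.09 ± 0.11). Their mean was -0.46 (adjusted p = 3.26e-06 by camera and adjusted p = 0.528 with an estimated correlation). It was -0.49 on slide 1, -0.52 on slide 2 and -0.47 with the slide as a block. MINDY1 and GABPB2 lay in a run of 25 genes, ENSA to PSMB4, with a median of -0.61, and the list mean was -0.23 (adjusted p = 0.132) with the median of neighbouring genes removed. Since the genes of this list are each other's neighbours, the removal takes out part of the list's own shift. Over all settings the adjusted p of the 7 lists ranged from 4.47e-16 to 0.874.

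**Figure D2:**
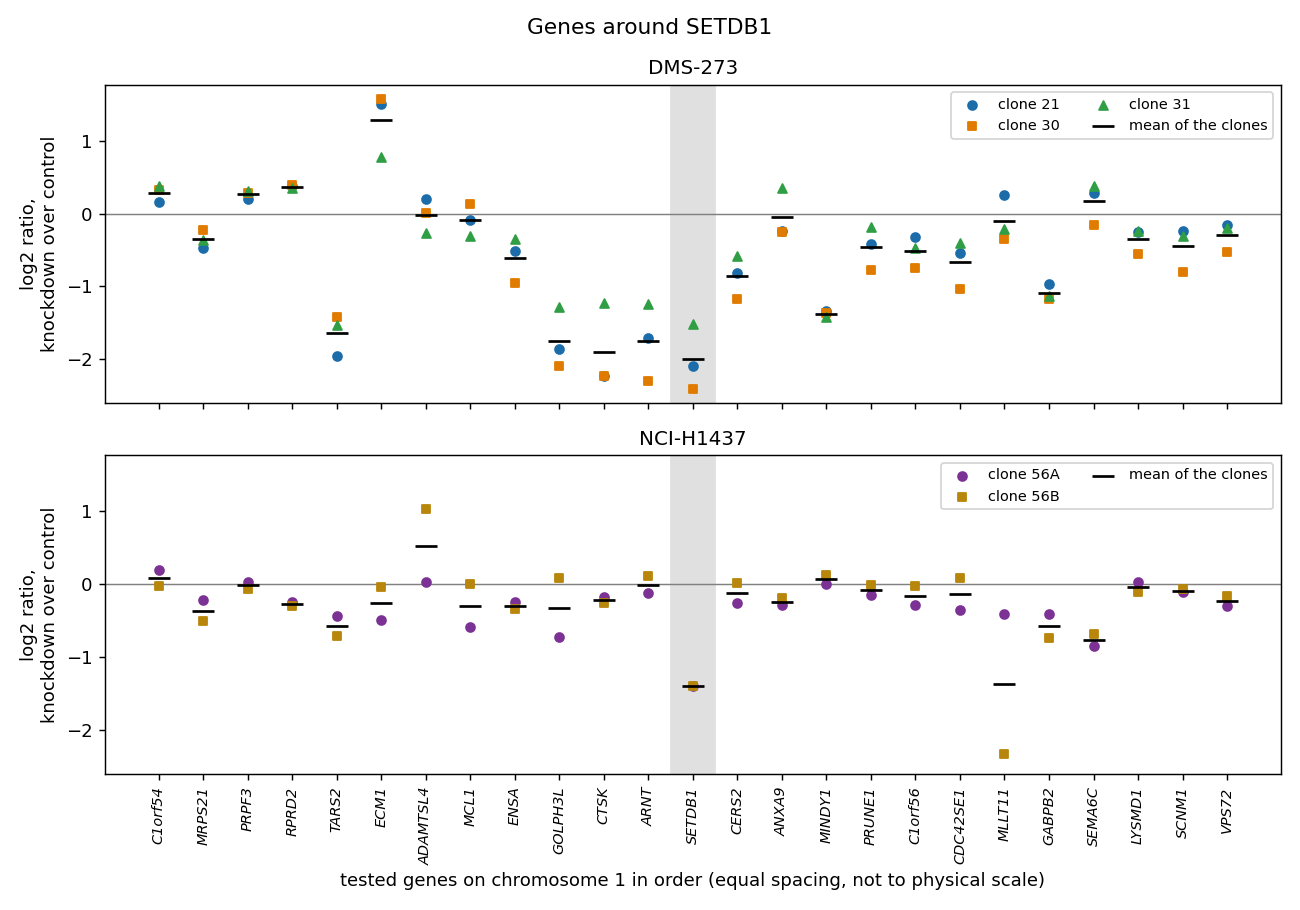
Log2 ratio of knockdown over control (vertical axis) for SETDB1, shaded, and the tested genes on either side in chromosome order (horizontal axis, equal spacing), with a point per clone and a black tick for the mean. In DMS-273 the neighbours GOLPH3L (-1.75), CTSK (-1.90) and ARNT (-1.75) lie near the ratio of SETDB1 (-2.01).

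The comparison in NCI-H1437 asked the same of the non-small cell line. The genes that rose most in NCI-H1437 included S100A7, which encodes psoriasin (3.55 ± 1.35), the basal keratins KRT14 (3.25 ± 0.22) and KRT17 (3.15 ± 0.20), and the kallikrein protease KLK8 (3.15 ± 0.93). The KRT14 probes ranged from 0.28 to 3.25. TFPI2, a serine protease inhibitor, rose by 3.22 ± 0.14, IGF2BP3, an oncofetal RNA-binding protein, by 3.23 ± 2.02 and NKD2, an antagonist of WNT signalling, by 3.16 ± 0.51. The long non-coding RNAs HOTAIRM1, of the HOXA cluster, and UCA1 rose by 3.16 ± 0.093 and 3.15 ± 0.17, COXFA4L3 by 3.53 ± 1.27 and CGA, the shared subunit of the glycoprotein hormones, by 3.41 ± 2.90. The cancer-testis antigen genes CTAG1A (-4.78 ± 0.094) and CTAG2 (-3.05 ± 0.15) fell, as did SRGN, a proteoglycan of secretory granules (-3.84 ± 0.74), and SPP1, which encodes osteopontin (-3.41 ± 0.90). The control signal of HOTAIRM1 was well above background on 1 of 3 arrays, and the knockdown signals of SLC16A4, ANTXR2 and NME8 on 2 of 3, so these ratios rest partly on signals near background. The placental hormone gene CSH1 fell to -3.38 ± 0.15, the mucosal peptide gene TFF3 to -2.66 ± 0.25, the monocarboxylate transporter SLC16A4 to -2.83 ± 0.64, the anthrax toxin receptor ANTXR2 to -2.72 ± 1.55 and NME8 to -2.99 ± 0.62. The TFF3 probes ranged from -2.66 to -0.94 and those of ANTXR2 from -2.72 to -0.78. CSMD1 was at least 6.92-fold lower and the calcium channel gene CACNA1H at least 6.22-fold lower, since their knockdown signal was not well above background. The small nucleolar RNA SNORD86 fell to -2.55 ± 0.17 and lay in a run of 25 genes on chromosome 20, ZCCHC3 to SNORD86, with a median of -1.13.

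Of 17587 genes tested in NCI-H1437, 3204 passed in the limma test, 1265 higher and 1939 lower, and 518 of these changed at least 2-fold. With median centring in place of loess 3080 passed, and the higher share was 28.2% in place of 39.5%. The fixed 2-fold rule on each of the 3 arrays took 293 genes, 117 higher and 176 lower, and it took 442 without clone 56A, 200 of them higher, and 419 without clone 56B, 201 of them higher. The passing genes had the same sign on slide 1 for 3204 of 3204 and on slide 2, with clone 56B alone, for 3199. Here too the call on these same arrays largely fixed the shared sign. With the slide as a block 5507 genes passed. Because the spread was pooled over both lines, the number that passed was 1620 without clone 21 and 1745 without clone 30 of DMS-273, and 149 with the line fitted alone. Fitted alone, S100A7, COXFA4L3, KLK8, IGF2BP3, CGA, SPP1 and ANTXR2 did not pass (adjusted p from 0.0566 to 0.184), nor did the list members RPL8 (0.0789), CEACAM6 (0.0652), PLEKHO1 (0.0732), ANP32E (0.0732), H2AC17 (0.125), PEG10 (0.0874) and PCDHB13 (0.0503). Neither did TFPI2 (0.102), ANTXR2 (0.0927), CGA (0.0661) and PCDHB13 (0.0634) with the scanner software's log ratio. The call of CGA was lost without clone 21, 30 or 31 of DMS-273 (adjusted p = 0.0805, 0.0746 and 0.0639), and over all settings the adjusted p of the 24 named genes ranged from 1.36e-06 to 0.184.

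Of the 29 lists, 4 shifted in NCI-H1437 with the preset correlation, 7 without clone 56A and 8 without clone 56B. With an estimated correlation camera passed 0, and 1 of the 29 had an unadjusted p under 0.05. Of 83 ribosomal protein genes, 17 rose and 4 fell (41 and 7 adjusted over the list alone), and RPL8 rose by 0.84 ± 0.043. Their mean was 0.20 (adjusted p = 4.37e-07 by camera and adjusted p = 0.971 with an estimated correlation). It was 0.23 on slide 1, 0.44 on slide 2 and 0.21 with the slide as a block. The 0.44 came from the array of clone 56B without dye correction, and the dye-corrected mean of that clone was 0.16. Of 44 epithelial genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone), including the mucin MUC1 (1.29 ± 0.074, with probes from 0.42 to 1.29) and the adhesion gene CEACAM6 (1.05 ± 0.086). Their mean was 0.37 (adjusted p = 3.58e-04 by camera and adjusted p = 0.971 with an estimated correlation). It was 0.27 on slide 1, 0.53 on slide 2 and 0.33 with the slide as a block. Of 41 genes near SETDB1 on chromosome 1, 0 rose and 8 fell (0 and 12 adjusted over the list alone), among them PLEKHO1 (-1.34 ± 0.35) and the histone chaperone ANP32E (-1.005 ± 0.16, with probes from -1.005 to -0.61). Their mean was -0.31 (adjusted p = 3.58e-04 by camera and adjusted p = 0.885 with an estimated correlation). It was -0.31 on slide 1, -0.40 on slide 2 and -0.30 with the slide as a block. With the median of neighbouring genes removed, which takes out part of this list's own shift, it was -0.055 (adjusted p = 0.824). Of 50 histone genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone), and H2AC17 was at -0.56 ± 0.16, with probes from -0.56 to -0.17. Their mean was -0.21 (adjusted p = 3.58e-04 by camera and adjusted p = 0.971 with an estimated correlation). It was -0.29 on slide 1, -0.023 on slide 2 and -0.23 with the slide as a block. The histone mean was -0.038 (adjusted p = 0.824) with the median of neighbouring genes removed, which takes out part of the shift of histone genes that lie side by side. Over all settings the adjusted p of the 4 lists ranged from 6.77e-18 to 0.971.

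**Figure D3:**
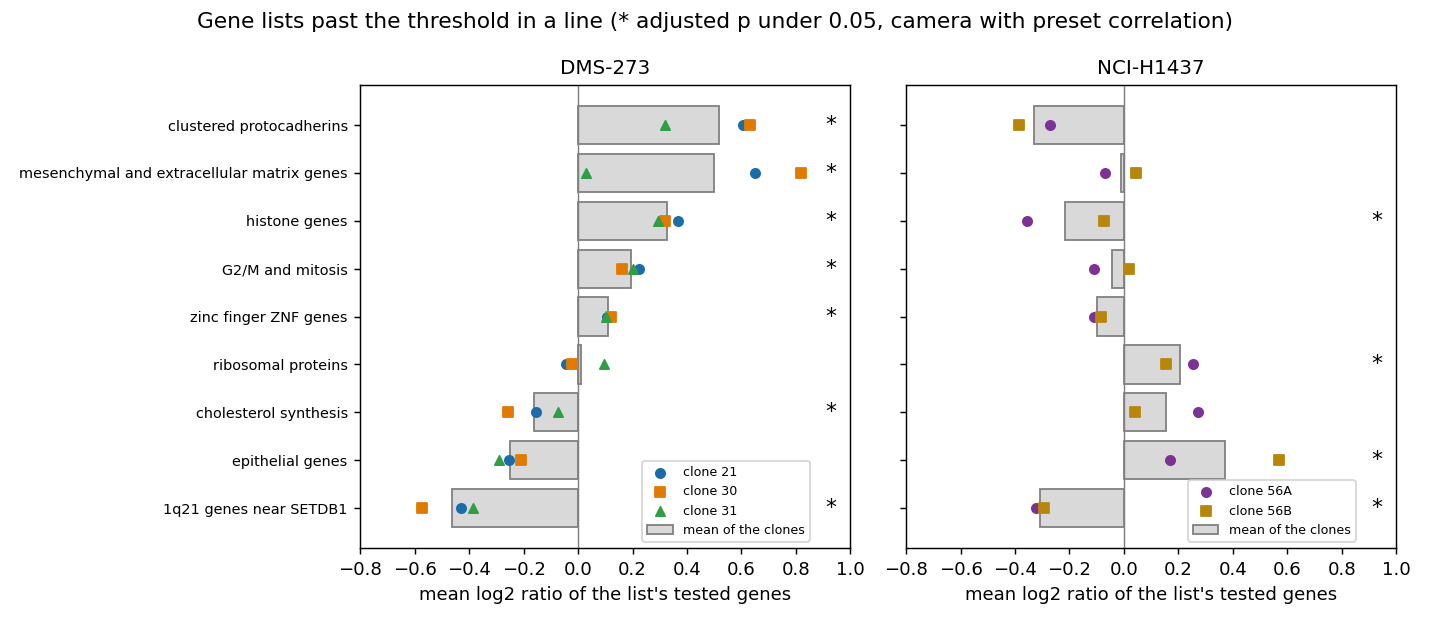
Mean log2 ratio of the tested genes of each gene list (horizontal axis) for the lists that passed in a line (vertical axis), with a grey bar for the mean of the clones and a coloured point per clone. Histone genes had means of 0.33 in DMS-273 and -0.21 in NCI-H1437, and the genes near SETDB1 had means of -0.46 and -0.31.

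The contrast of both lines asked whether the small cell and the non-small cell line responded differently. CSH1 rose in DMS-273 (2.43 ± 0.89) and fell in NCI-H1437 (-3.38 ± 0.15), a difference of 5.81 (adjusted p = 0.00222), and PCDHB13 did likewise (2.62 ± 1.06 and -1.89 ± 0.38, difference 4.51, adjusted p = 0.00693). On the dye-swap arrays CSH1 was at 1.53 in DMS-273 and -4.24 in NCI-H1437, a gap to its means that the SD of the dye-corrected clones leaves out. In NCI-H1437 the PCDHB13 call was lost without clone 21, 30, 56A or 56B (adjusted p = 0.0515, 0.0601, 0.0819 and 0.120). GDF15, a stress-induced cytokine, rose by 0.74 ± 0.083 in DMS-273 and fell to -2.14 ± 0.011 in NCI-H1437, a difference of 2.88 (adjusted p = 3.29e-04). The imprinted gene PEG10 (1.01 ± 0.10 and -0.82 ± 0.16) and the cancer-testis gene MAGEA1 (0.71 ± 0.23 and -1.66 ± 0.23) had the same pattern, with differences of 1.83 and 2.37 (adjusted p = 0.00145 and 0.00165). The rise of MAGEA1 in DMS-273 did not pass without clone 21 or 30 (adjusted p = 0.0780 and 0.0796). The ratios of histone genes were higher by a mean of 0.52 in DMS-273 than in NCI-H1437 (adjusted p = 1.32e-12 by camera), and the mean difference of epithelial genes was -0.47 (adjusted p = 5.41e-04). With an estimated correlation these were adjusted p = 0.777 and 0.777. Of the 44 epithelial genes, 22 were tested in DMS-273, so part of their difference rests on signals near background there. The genes near SETDB1 (mean difference -0.16, adjusted p = 0.350) and the mesenchymal genes (0.47, adjusted p = 0.140) were not shown to differ.

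Of 20782 genes tested in either line, 2868 had ratios that differed between the lines in the limma test, 1548 with a higher and 1320 with a lower ratio in DMS-273. With the median of neighbouring genes removed this balance turned, with 795 higher and 961 lower. The number was 551 without clone 21, 712 without clone 30, 1917 without clone 31 and 5162 with the slide as a block. Of 15722 genes tested in both lines, 291 fell in both where independence gave 153, and 134 rose in both where it gave 82.2. Another 146 rose in DMS-273 and fell in NCI-H1437, and 115 did the opposite, where independence gave 126 and 99.2. The calls of both lines share 1 estimate of spread per gene, so they are not independent by design. An excess over these expected numbers therefore does not by itself show a shared response. Across these genes, which are not independent replicates, the ratios of the lines had r = 0.0912 (Spearman's rho 0.119). IGFBP7 rose in both lines (2.52 ± 1.37 and 3.11 ± 0.71), and in NCI-H1437 its call was lost without clone 56B (adjusted p = 0.0676), while in DMS-273 it was lost without clone 21 or 30 (0.115 and 0.0926). With an intensity trend and robust prior IGFBP7 passed in neither line (adjusted p = 0.342 in DMS-273 and 0.337 in NCI-H1437). CTAG1A (-2.43 and -4.78) and CTAG2 (-1.83 ± 0.96 and -3.05) fell in both, although the DMS-273 calls were lost without clone 30 (adjusted p = 0.122 and 0.0922). NINJ1 (-2.36 and -0.96 ± 0.28), SUSD3 (-2.33 and -1.01 ± 0.51) and VEGFD (-2.64 and -0.97 ± 0.13) also fell in both. TXNIP, an inhibitor of thioredoxin, fell to -0.89 ± 0.23 and -1.16 ± 0.10, and the tetraspanin TSPAN7 to -1.19 ± 0.18 and -1.57 ± 0.28. TSPAN7 lay in X chromosome runs of 25 genes with medians of -0.47 in DMS-273 and -1.01 in NCI-H1437. With NCI-H1437 fitted alone NINJ1 (adjusted p = 0.0888), SUSD3 (0.118), VEGFD (0.0732), TXNIP (0.0573) and TSPAN7 (0.0532) did not pass there, nor did VEGFD with the intensity trend and robust prior (0.0531). With the median of neighbouring genes removed VEGFD was at -0.39 in NCI-H1437 and did not pass (adjusted p = 0.223), while TXNIP and TSPAN7 moved to -0.76 and -0.81 there and passed. Over all settings the highest adjusted p of these 8 genes was 0.342 in DMS-273 and 0.337 in NCI-H1437, and the lowest were 7.22e-06 and 4.77e-05. IGFBP7, TXNIP and TSPAN7 were singled out as shared after their values were seen.

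The lists in this paragraph did not shift in either line in the camera test, and single members that passed are given as counts. HOX genes, which pattern the body axis, had 2 higher and 0 lower of 20 in DMS-273 and 5 higher and 1 lower of 10 in NCI-H1437 (adjusted p = 0.649 and 0.240). These were 2 and 0, and 5 and 1, adjusted over the list alone. HOXA3 rose by 2.56 ± 0.50 in NCI-H1437. Cancer-testis and germline genes had 5 higher and 4 lower of 24 in DMS-273 and 4 higher and 6 lower of 24 in NCI-H1437 (adjusted p = 0.754 and 0.874). These were 5 and 5, and 6 and 6, adjusted over the list alone. Genes derived from endogenous retroviruses had 4 higher and 3 lower of 15 in DMS-273 and 0 higher and 2 lower of 9 in NCI-H1437 (adjusted p = 0.754 and 0.874). These were 4 and 4, and 0 and 2, adjusted over the list alone. Imprinted genes had 7 higher and 4 lower of 31 in DMS-273 and 3 higher and 2 lower of 22 in NCI-H1437 (adjusted p = 0.375 and 0.520). These were 9 and 5, and 3 and 3, adjusted over the list alone. Interferon response genes had 3 higher and 3 lower of 39 in DMS-273 and 2 higher and 5 lower of 41 in NCI-H1437 (adjusted p = 0.909 and 0.966). These were 2 and 3, and 2 and 5, adjusted over the list alone. USP18, a negative regulator of interferon signalling, fell to -0.91 ± 0.27 in DMS-273. Antigen presentation genes had 0 higher and 1 lower of 21 in DMS-273 and 0 higher and 2 lower of 21 in NCI-H1437 (adjusted p = 0.734 and 0.966). These were 0 and 0, and 0 and 0, adjusted over the list alone. Inflammatory and NF-kB genes had 0 higher and 0 lower of 10 in DMS-273 and 1 higher and 1 lower of 28 in NCI-H1437 (adjusted p = 0.754 and 0.874). These were 0 and 0, and 1 and 1, adjusted over the list alone. The partners of SETDB1 in H3K9 methylation and silencing had 3 higher and 3 lower of 33 in DMS-273 and 2 higher and 4 lower of 34 in NCI-H1437 (adjusted p = 0.556 and 0.751). These were 3 and 3, and 3 and 4, adjusted over the list alone. Mean, median and test differed in sign for cancer-testis genes in DMS-273 (mean -0.10, median 0.04, test up), retrovirus-derived genes in DMS-273 (mean 0.0054, median -0.10, test down), interferon genes in DMS-273 (mean 0.07, median -0.027, test up), interferon genes in NCI-H1437 (mean 0.032, median 0.0034, test down) and antigen presentation in NCI-H1437 (mean 0.035, median 0.042, test down).

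The lists in this paragraph, of cell identity and growth, did not pass in either line. Neuroendocrine and neuronal genes had 9 higher and 8 lower of 43 in DMS-273 and 3 higher and 1 lower of 15 in NCI-H1437 (adjusted p = 0.556 and 0.995). These were 12 and 9, and 4 and 1, adjusted over the list alone. The microtubule gene MAP2 (2.15 ± 0.15) and the adhesion gene NCAM1 (1.06 ± 0.062, with probes from 0.26 to 1.06) rose in DMS-273, whereas the neurofilament gene NEFM fell (-1.58 ± 0.21). Lung lineage genes had 3 higher and 2 lower of 12 in DMS-273 and 1 higher and 4 lower of 19 in NCI-H1437 (adjusted p = 0.556 and 0.751). These were 3 and 2, and 1 and 4, adjusted over the list alone. WNT pathway genes had 8 higher and 7 lower of 44 in DMS-273 and 5 higher and 7 lower of 39 in NCI-H1437 (adjusted p = 0.754 and 0.874). These were 9 and 7, and 6 and 9, adjusted over the list alone. YAP/TEAD target genes had 5 higher and 3 lower of 24 in DMS-273 and 3 higher and 1 lower of 25 in NCI-H1437 (adjusted p = 0.191 and 0.146). These were 7 and 4, and 3 and 0, adjusted over the list alone. The p53 target genes had 3 higher and 4 lower of 33 in DMS-273 and 0 higher and 2 lower of 32 in NCI-H1437 (adjusted p = 0.833 and 0.751). These were 5 and 4, and 0 and 2, adjusted over the list alone. Replication genes of S phase had 4 higher and 3 lower of 51 in DMS-273 and 5 higher and 10 lower of 51 in NCI-H1437 (adjusted p = 0.151 and 0.456). These were 4 and 2, and 5 and 12, adjusted over the list alone. Tumour suppressor genes silenced in lung cancer had 2 higher and 3 lower of 18 in DMS-273 and 4 higher and 0 lower of 15 in NCI-H1437 (adjusted p = 0.649 and 0.240). These were 2 and 3, and 4 and 0, adjusted over the list alone. CADM1, a cell adhesion gene of that list, was at least 3.14-fold higher in NCI-H1437, where its control was not well above background and its probes ranged from 0.74 to 1.65. Signs of mean, median and test differed for lung lineage genes in NCI-H1437 (mean -0.12, median 0.0011, test down), WNT genes in NCI-H1437 (mean 0.028, median -0.012, test down) and neuroendocrine genes in NCI-H1437 (mean 0.27, median -0.21, test down).

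The lists of stress, hypoxia and glycolysis, metallothioneins and markers of other cell types did not pass in either line. Unfolded protein and amino acid stress genes had 3 higher and 5 lower of 44 in DMS-273 and 1 higher and 9 lower of 44 in NCI-H1437 (adjusted p = 0.361 and 0.0534). These were 3 and 5, and 1 and 9, adjusted over the list alone. TRIB3, a stress-induced pseudokinase, fell to -2.49 ± 0.45 in NCI-H1437 and lay in the chromosome 20 run ZCCHC3 to SNORD86 with a median of -1.13. Hypoxia and glycolysis genes had 2 higher and 5 lower of 39 in DMS-273 and 2 higher and 4 lower of 40 in NCI-H1437 (adjusted p = 0.649 and 0.965). These were 2 and 5, and 0 and 3, adjusted over the list alone. Metallothionein genes had 0 higher and 1 lower of 10 in DMS-273 and 0 higher and 2 lower of 11 in NCI-H1437 (adjusted p = 0.408 and 0.157). These were 0 and 1, and 0 and 2, adjusted over the list alone. Leukocyte markers had 2 higher and 0 lower of 11 in DMS-273 and 0 higher and 1 lower of 14 in NCI-H1437 (adjusted p = 0.649 and 0.966). These were 2 and 0, and 0 and 1, adjusted over the list alone. Endothelial markers had 0 higher and 1 lower of 7 in DMS-273 and 1 higher and 1 lower of 5 in NCI-H1437 (adjusted p = 0.754 and 0.751). These were 0 and 1, and 1 and 1, adjusted over the list alone. The remaining lists passed in the other line alone, and their differences between the lines were tested separately. Epithelial genes in DMS-273 had 1 higher and 5 lower of 22 (adjusted p = 0.556, 1 and 5 adjusted over the list alone). Ribosomal protein genes in DMS-273 had 5 higher and 7 lower of 84 (adjusted p = 0.754, 3 and 7 adjusted over the list alone). In NCI-H1437, mitosis genes had 1 higher and 5 lower of 64 (adjusted p = 0.966, 1 and 4 adjusted over the list alone), ZNF genes had 10 higher and 39 lower of 298 (adjusted p = 0.112, 7 and 34 adjusted over the list alone), protocadherins had 0 higher and 1 lower of 6 (adjusted p = 0.874, 0 and 1 adjusted over the list alone). There, mesenchymal genes had 2 higher and 3 lower of 25 (adjusted p = 0.966, 2 and 3 adjusted over the list alone) and cholesterol synthesis genes had 3 higher and 1 lower of 31 (adjusted p = 0.110, 2 and 1 adjusted over the list alone), and EBP of the latter was at -0.51. Mean, median and test had unlike signs for epithelial genes in DMS-273 (mean -0.25, median 0.035, test down), leukocyte markers in DMS-273 (mean 0.059, median -0.0099, test up), leukocyte markers in NCI-H1437 (mean -0.052, median 0.01, test down), mitosis genes in NCI-H1437 (mean -0.046, median 0.0024, test down) and mesenchymal genes in NCI-H1437 (mean -0.013, median 0.15, test up).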

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

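The tests of a shared local response, in the nearest genes and in the wider list, of contiguous genes, of chance order and of the X chromosome were chosen after the results were seen.

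These results drew attention because the ratio of knockdown clones over control differed between the lines in the test of the difference itself, which covered 20782 genes and 29 lists. It passed for 71 of the 92 genes named, 36 higher and 35 lower in DMS-273, with adjusted p up to 0.0422 by limma, and for 7 lists. The named genes were picked largely by low p for this difference, by extreme ratios in a line or by low p within a list. That choice favoured passing, and over all genes tested 2868 of 20782 passed (13.8%). Values in brackets are the DMS-273 log2 ratio minus that of NCI-H1437. Higher and lower refer here to these ratios of knockdown over control and not to levels of expression. SPP1 and SRGN, for instance, fell in NCI-H1437 and were not tested in DMS-273. HEPACAM2 and PTPRZ1 fell in DMS-273 and were not tested in NCI-H1437. Of the 71 genes, 14 were tested in DMS-273 alone and 17 in NCI-H1437 alone, since in the other line neither channel was well above background on every array. For CSMD1, CACNA1H and CADM1 a channel was not well above background in NCI-H1437, and for LCP1 the control was not well above background in DMS-273, so their differences are fitted values and no bounds. The dimmer channel was above background on 1 of 4 arrays for MAL2 and P2RY14 in DMS-273 and on 1 of 3 for HOTAIRM1 in NCI-H1437.

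Hormone, secreted and stress genes with a higher ratio in DMS-273 were CSH1 (5.81), SPP1 (3.46), SRGN (3.82), TFF3 (1.92), GDF15 (2.88) and TRIB3 (2.15). Adhesion, membrane and matrix genes were PCDHB13 (4.51), PCDHB9 (1.01), NCAM1 (1.00), ANTXR2 (3.94), CSMD1 (2.82), LRRC32 (2.47), COL1A2 (2.33) and PDGFRA (1.59). Transport and channel genes were CACNA1H (2.80), CACNG6 (2.04) and SLC16A4 (2.68). The regulators of transcription BCL6 (2.84), MYOD1 (2.50) and ZNF24 (0.91) had higher ratios too, as had MAP2 (2.46), LCP1 (2.55), SHFL (3.59), NME8 (3.00), MAGEA1 (2.37) and PEG10 (1.83). RNA genes were D21S2088E (3.84) and SNORD86 (3.17). Histone and chromatin genes were H4C11 (1.37), H3C2 (1.26), H2AC17 (0.80) and ANP32E (1.07), and PLEKHO1 had 1.52. FAM110A (2.30), SNRPB (1.73), TRIB3 and SNORD86 lay between ZCCHC3 and SNORD86 on chromosome 20, a run with a median of -1.13 in NCI-H1437, and FASTKD5 had 1.97.

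Keratin, psoriasin and kallikrein genes with a lower ratio in DMS-273 than in NCI-H1437 were S100A7 (-3.54), KRT14 (-3.26), KRT17 (-3.05), KRT42P (-3.20) and KLK8 (-3.25), of which KRT42P is a pseudogene. The KRT42P probes ranged from -0.10 to 3.21 in NCI-H1437. Epithelial and adhesion genes were MUC1 (-0.91), CEACAM6 (-1.11), CADM1 (-1.72), HEPACAM2 (-3.59), MAL2 (-3.62) and NINJ1 (-1.41). Signalling and growth factor genes were VEGFD (-1.67), CCN5 (-2.23), NKD2 (-2.91), P2RY14 (-2.50), RASGRP1 (-2.25) and PTPRZ1 (-2.81). Regulators of transcription, RNA-binding genes and non-coding RNAs were HOXA3 (-2.45), HOTAIRM1 (-3.02), UCA1 (-3.11), IGF2BP3 (-3.06), ZFP42 (-2.17) and ARNT (-1.75). Proteases and their inhibitors were TFPI2 (-2.55), FAP (-2.20) and CTSK (-1.69), and the remaining genes were COXFA4L3 (-3.50), DAPL1 (-2.97), ASB9 (-3.02), SLC2A5 (-2.09), NEFM (-1.52), COBL (-2.33), SUSD3 (-1.32), GOLPH3L (-1.43) and MINDY1 (-1.44).

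Among the lists, camera with the preset correlation gave differences of the mean ratio in DMS-273 from that in NCI-H1437, over genes tested in either line. Of 17 protocadherins 6 were tested in NCI-H1437 (mean -0.33), and of 429 ZNF genes 298 (mean -0.097). Of 44 epithelial genes 22 were tested in DMS-273 (mean -0.25). Part of these differences therefore rests on signals near background in 1 line. The list means moved apart for histone genes by 0.52 (0.32 and -0.20, adjusted p = 1.32e-12, and adjusted p = 0.777 with an estimated correlation), protocadherins by 0.63 (0.52 and -0.11, adjusted p = 0.00256, and adjusted p = 0.777 with an estimated correlation), mitosis genes by 0.24 (0.19 and -0.046, adjusted p = 1.35e-04, and adjusted p = 0.777 with an estimated correlation) and ZNF genes by 0.19 (0.11 and -0.076, adjusted p = 1.87e-05, and adjusted p = 0.128 with an estimated correlation). They were lower in DMS-273 for epithelial genes by -0.47 (-0.10 and 0.37, adjusted p = 5.41e-04, and adjusted p = 0.777 with an estimated correlation), cholesterol synthesis genes by -0.32 (-0.16 and 0.15, adjusted p = 6.86e-04, and adjusted p = 0.777 with an estimated correlation) and ribosomal protein genes by -0.20 (0.009 and 0.21, adjusted p = 4.33e-05, and adjusted p = 0.777 with an estimated correlation). The difference of the ribosomal protein genes was 0.10 on slide 1 (0.33 and 0.23) and -0.44 on slide 2 (-0.0074 and 0.44), both without dye correction, and -0.21 with the slide as a block. The 0.33 and the 0.44 came from forward arrays alone, with no dye-swap array to offset the dye effect. With dye correction the means on slide 1 were -0.044 and 0.095 in clones 21 and 31 and 0.25 in clone 56A. On slide 2 they were -0.024 in clone 30 and 0.16 in clone 56B. The opposite sign on slide 1 did not hold with dye correction. On slide 1 and slide 2 the other differences were histone genes 0.63 and 0.34, protocadherins 0.61 and 0.69, mitosis genes 0.26 and 0.19, ZNF genes 0.19 and 0.18, epithelial genes -0.38 and -0.61 and cholesterol synthesis genes -0.37 and -0.19.

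The call of a difference was lost without clone 21 for ANTXR2 (0.0593), ARNT (0.0743), COXFA4L3 (0.0523), CTSK (0.0780), FAP (0.0587), GOLPH3L (0.120), H2AC17 (0.0697) and IGF2BP3 (0.140), where brackets hold the adjusted p. Without clone 21 it was also lost for MYOD1 (0.0984), PCDHB9 (0.0510), S100A7 (0.0542), SHFL (0.0680), SUSD3 (0.0694), TFF3 (0.0505) and ZNF24 (0.0586). Without clone 30 it was lost for ANTXR2 (0.0503), CTSK (0.0713), GOLPH3L (0.0957), H2AC17 (0.0525), IGF2BP3 (0.132), SHFL (0.0803) and SUSD3 (0.0629), and without clone 31 for IGF2BP3 (0.0968). MYOD1 was lost without clone 56A (0.0546) or 56B (0.0567), and SHFL without clone 56B (0.0520). With the software's own log ratio 14 of the differences did not pass, CCN5 (0.172), ANTXR2 (0.0934), VEGFD (0.0904), GOLPH3L (0.0868), CEACAM6 (0.0854), COXFA4L3 (0.0749) and CTSK (0.0623), and TFF3 (0.0583), FAP (0.0579), IGF2BP3 (0.0574), KRT17 (0.0534), SHFL (0.0513) and ARNT (0.0512), besides TFPI2, whose difference was then -0.27 (adjusted p = 0.915). With an intensity trend and robust prior 6 did not pass, D21S2088E (0.171), TFPI2 (0.109), MYOD1 (0.0978), COL1A2 (0.0658), MUC1 (0.0655) and IGF2BP3 (0.0646), and with the deposited table TFPI2 did not (0.0617). The cause of these losses was not tested. Over all settings the adjusted p of the 71 genes ranged from 5.69e-06 to 0.915.

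The genes beside SETDB1 fell with it in DMS-273: GOLPH3L (-1.75 ± 0.42), CTSK (-1.90 ± 0.58), ARNT (-1.75 ± 0.53), CERS2 (-0.86 ± 0.29) and ENSA (-0.61 ± 0.32), although without clone 21 CERS2 (adjusted p = 0.0705) and ENSA (0.121) did not pass, nor ENSA without clone 30 (0.0636). The median of the nearest 10 tested genes was -0.73 in DMS-273 (-0.66, -1.07 and -0.53 in clones 21, 30 and 31) with 8 called lower, against -0.19 with 0 called by limma in NCI-H1437. For these 10 genes a local response shared by both lines, scaled by the fall of SETDB1 at its brightest probe, required -0.51 in NCI-H1437. The measured median was -0.19, with -0.25 in clone 56A and -0.011 in clone 56B. Both clones lay above the value that this probe required, which argued against a shared response of that size. The other SETDB1 probes (-2.77 and -2.51 in DMS-273, -1.40 and -1.25 in NCI-H1437) would require a smaller fall, which was not tested. The SE of 0.0417 was taken over neighbouring genes, which are not independent, and 2 clones leave a smaller shared response open. For the wider list of genes near SETDB1 a shared response stays open. The list's mean in NCI-H1437 was -0.31 (SE 0.0569 over its genes, 37 of 41 below 0), near the -0.32 that the -0.46 of DMS-273 required. The list was not shown to differ between the lines (adjusted p = 0.350 by camera). The median intensity percentile of 84.4 argued against dim probes. Consecutive genes fell in each clone over 5 tested genes from ENSA to CERS2 (permutation p = 0.013, 1000 shuffles), but the test was prompted by this run and its shuffles break the link between neighbours, so it decides nothing. The 25 genes ENSA to PSMB4 had medians of -0.55 on slide 1 and -0.67 on slide 2. Fewer copies of this segment in the DMS-273 clones than in their control and a local response of DMS-273 cannot be told apart, since copy number was not measured.

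Runs of 25 neighbouring genes moved one way, such as ZCCHC3 to SNORD86 on chromosome 20 (-1.13 in NCI-H1437 and 0.18 in DMS-273), SCARNA9L to MID1IP1 on X (-1.01 and -0.43), PLAG1 to SNHG6 on chromosome 8 (0.67 and 0.26) and H4C2 to H3C8 on chromosome 6 (-0.20 and 0.54). The spread of window medians exceeded that of each of 1000 shuffles in both lines (permutation p = 0.001, the smallest they can give), which excluded a chance order of genes, and 459 of 13213 overlapping windows in DMS-273 and 886 of 12461 in NCI-H1437 passed the shuffled limit. A regional response shared by both lines was argued against by the correlation of the window medians, r = 0.149 over all windows (51 of 1000 rotations gave as high a value) and r = 0.157 on the X chromosome, although single runs such as PRPS2 to SCML1 on X fell in both (-0.56 in DMS-273 and -0.73 in NCI-H1437). Within the strongest windows at least 83.3% of the genes shared the sign at each level of intensity, a share that the choice of windows by their medians largely fixed. Copy-number differences between clones and control and a regional response particular to a line cannot be told apart for these runs, since DNA was not measured.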

How the results depend on the processing

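The removal of the neighbouring median and the restriction to genes of known position were chosen after the data were seen. SETDB1 passed as lower in both lines under each alternative run on it. Of the values per setting for named genes and lists, 7414 kept direction and side of the threshold, 547 kept direction and no longer passed, 133 newly passed and 1 reversed, and of the counts 148 stayed within 1.5 times and 34 did not.

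With the software's log ratio 2059, 1706 and 1643 genes passed in DMS-273, in NCI-H1437 and for the difference, and the 2-fold rule took 489 and 689. With 1 dye effect for both lines the numbers were 5324, 5904 and 6009. With the slide as a block 5507 passed in NCI-H1437, 5162 for the difference and 7 lists in NCI-H1437. With no filter on dim probes 9 lists passed in NCI-H1437. For these the cause was not tested. With each line fitted alone 149 passed in NCI-H1437, a fit with 2 samples. An adjusted p under 0.01 left 1046 and 960 genes, and 1.5-fold took 627 and 1012. Camera with an estimated correlation called 0 and 0 lists, with 1 list per line at an unadjusted p under 0.05. With the neighbouring median removed 1724 passed in NCI-H1437 (49.9% higher), 1756 for the difference (795 higher and 961 lower), 188 by the 2-fold rule in NCI-H1437 and 4 lists in DMS-273. Part of this came with the smaller gene set, since genes of known position alone gave 2431, 2290 (1226 higher), 243 and 6. EBP in NCI-H1437 reversed to 0.10 (adjusted p = 0.478), and the cause was not tested. With the replicate number as a block 2052 genes differed, a pairing that the labels do not give.

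The fits without 1 clone kept the dye-swap pool, which holds that clone. Without 1 clone at a time the passing genes ranged from 503 to 5042 in DMS-273, 1620 to 2710 in NCI-H1437 and 551 to 2732 for the difference. The 5042 came without clone 56A or 56B, as with DMS-273 fitted alone, where the spread of the DMS-273 clones alone entered the fit. The 2-fold rule took 192 to 324 and 293 to 442 genes. Passing lists ranged from 6 to 8 and from 4 to 8, and SETDB1 from -2.13 to -1.90 and from -1.403 to -1.398. Without a clone of NCI-H1437 the lone clone was assumed to vary like those of DMS-273. Signal over background limits the rest, since 46.1% to 59.7% of spots per channel were well above it.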

Other observations

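The comparisons of lists between clones and of chromosome medians, and the tests of slide, of opposite changes and of interferon, mesenchymal and YAP/TEAD genes in clone 31, were chosen after the values were seen.

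Inflammatory and NF-kB genes had unlike means in the clones of NCI-H1437, -0.90 in clone 56A and 1.09 in clone 56B. Metallothioneins, which bind metals, had means of -1.38 and 0.24 there, and 0.65, 0.99 and 0.11 in clones 21, 30 and 31 of DMS-273. YAP/TEAD targets had means of 0.52 and 0.67 in clones 21 and 30 and 0.064 in clone 31. Antigen presentation genes had means of -0.0079, 0.29 and -0.50 in clones 21, 30 and 31. Clones 56A and 56B were hybridized on different slides, so clone and slide cannot be separated for them, and differences between single clones were not tested.

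Whole chromosomes had unlike medians. The X chromosome genes had a median of -0.32 in DMS-273 (503 genes, clones from -0.52 to -0.20) and -0.11 in NCI-H1437 (449 genes). Chromosome 16 had a median of -0.29 in NCI-H1437 and -0.019 in DMS-273. Chromosome 8 stood above 0 in both lines, with medians of 0.17 and 0.20. On chromosome 20 the median was 0.18 in DMS-273 and 0.0051 in NCI-H1437.

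Clone 31 of DMS-273 differed from clones 21 and 30, with r = 0.713 and 0.676 to them across 18917 genes against 0.896 between them, and its ratios had a slope of 0.665 on their mean, near the 0.673 of SETDB1. The slide was argued against, since clone 21 correlated better with clone 30 on the other slide than with clone 31 on its own, by 0.183. Chromosome-scale shifts of its own were argued against, since r with clone 21 stayed at 0.710, against 0.902 between clones 21 and 30, when neighbouring medians were removed. A weaker knockdown that scales every change down was argued against as the whole cause, since it required means of 0.47 for mesenchymal and 0.38 for YAP/TEAD genes in clone 31, where 0.029 and 0.064 were measured. Of 29 lists, 16 lay more than 2 standard errors of their genes from the scaled value, 11 below and 5 above, at a slope of 0.647 on dye-corrected ratios, and each of the 16 by more than the gap between clones 21 and 30. Clone 30 scaled from clone 21 gave 12 such lists by standard errors alone. Interferon response genes took the other sign, with a mean of -0.36 in clone 31 against 0.19 and 0.38 in clones 21 and 30. The scatter was 1.43 times that between clones 21 and 30, under the limit of 1.5 times set beforehand, and so went with scaling. Of 428 genes of at least 2-fold in clones 21 and 30, 213 were so in clone 31 and 27 had the opposite sign there, 1 of them by at least 1.5-fold, which decides nothing. A weaker knockdown may account for part of the difference, and changes particular to clone 31 stay open and untested.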
